A study of Mus musculus with 12 samples.

How the data were processed

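The material was RNA from mouse peritoneal macrophages enriched through CD11b, pooled from 3 male C57BL/6 mice at each of 12 sampling times, 6 circadian times on each of 2 days in constant darkness. The deposited table holds log2 values of 35557 probe sets on 12 arrays of Affymetrix whole-transcript type, per the labels' protocols, and these were made with RMA, per the submitters' processing notes. RMA corrects background, normalises arrays to a common distribution and summarises probes on a log2 scale. The software version, the probe annotation used and any filter applied by the authors are not given in the sources used here, and no scanner files were used here. The values were taken as deposited. Because pools of mice were measured, the spread between arrays of a time is that between pools on separate days, and the spread between single mice was not measured.

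Probe sets were named through the platform annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 were unnamed in that table, and 21698 of those with 1 symbol matched a gene ID in a mouse gene table of assembly GRCm38.p6, used for names only, with 0 symbols changed. No gene was named from a probe set with several symbols. For 999 genes with several probe sets, up to 77, the brightest probe set on average over all arrays was used, which left 19938 genes. No filter on dim genes was applied.

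Rhythmic genes were found with limma 3.58.1 in R 4.3.3: a cosine and a sine of circadian time with a period of 24 h were fitted to all 12 arrays, and an F test of both terms used variances moderated with a trend on expression level. Amplitudes are given as the fitted peak-to-trough difference, with a delta-method SE, and peaks as circadian time with their SE. The same tool gave an F test over 6 groups of 2 arrays per circadian time, the difference of day 2 from day 1 beside the wave, and an F test of day-by-wave terms. The wave fit was repeated at periods of 48, 16, 12 and 9.6 h, which are orthogonal to 24 h in this sampling. All p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05.

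A total of 34 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternatives: core clock, clock output factors, TLR4 signalling, inflammatory cytokines and mediators, pattern recognition receptors, immediate early, heat shock, cold-inducible, unfolded protein response, glucocorticoid-responsive, cholesterol synthesis, lipid handling, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, proteasome, cell cycle, interferon-stimulated, MHC class II presentation, lysosome and autophagy, complement and phagocytic receptors, antioxidant response, adhesion and migration receptors, and markers of large and small peritoneal macrophages, B cells, T and NK cells, mast cells, neutrophils, eosinophils, dendritic cells, mesothelial cells and fibroblasts, erythroid cells and platelets. For each list, rhythmic members were counted over all genes and adjusted over the list alone, enrichment was tested by a two-sided Fisher's exact test against the other genes tested, and the mean of gene-centred values per array was tested for a 24 h wave by 100000 permutations of the circadian times. Differences between days were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Each family of list tests was adjusted over the 34 lists. Fisher's exact test treats the genes of a list as independent, which genes that vary together are not, while the permutation test takes arrays as its units.

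Genes were named by rule: all measured core clock and clock output genes, the 15 other rhythmic genes with the largest peak-to-trough difference, up to 4 rhythmic members of each other list by smallest p, and up to 4 members of each cell type list by mean level. Day comparisons would have named genes past the threshold, of which there were 0. Genes named in the closing section outside this rule are said there to have been chosen after their values were seen.

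The day number in the labels marks arrays of a shared day in darkness. Deviations of arrays from the mean of their circadian time were compared between arrays of day 1: the 15 correlations ran from -0.094 to 0.172 with a median of -0.005, and 2 exceeded 0.1. The day therefore entered as a block in an alternative fit only, as set before.

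Alternatives were a filter on dim genes, the mean of a gene's probe sets, all probe sets tested, another quantile normalization and median centring. Further ones were no variance trend, array weights, leaving out each array, and the day as a block with and without linear elapsed time. Last were an added 12 h wave, with both waves tested jointly, and other thresholds. After seeing the data, fits without the 4 arrays of lowest spread and with each array's spread as a covariate were added. The scripts were tested on simulated data of 19938 genes with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold: for the 24 h rhythm, 35.8% of genes of 1.5-fold, 77.6% of 2-fold and 95.5% of 4-fold size were recovered with 4 false calls among 143. For a level raised at 1 circadian time, 16.4%, 43.3% and 90.9% were recovered. For the day difference, 67.2% of 1.5-fold changes were recovered, and for a wave that differed between days, 1.49% at 2-fold and 47.0% at 4-fold, so that this last test can miss large differences. The simulated noise was drawn independently for each gene and array, without low-spread arrays or correlation between genes. The share of false calls in the simulation therefore does not carry over to the real calls. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.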

Results

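The series followed gene expression in mouse peritoneal macrophages, the resident phagocytes of the abdominal cavity, across 48 h of constant darkness. Male C57BL/6 mice had been held in a light-dark cycle before release into darkness, so that circadian time 0 (CT0) marks the start of the subjective day and CT12 the start of the subjective night. Cells were washed from the peritoneal cavity every 4 h and enriched on magnetic columns through CD11b, an integrin carried by macrophages and other myeloid cells. RNA of 3 mice was pooled at each time and hybridised to 1 whole-transcript array, which gave 12 arrays: 6 circadian times, each sampled on day 1 and on day 2 (n = 2 per time). The median log2 value of an array lay between 6.25 and 6.36. The number of arrays limits the precision of every value given here.

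Arrays taken at the same circadian time on the 2 days correlated at 0.987 at CT0, 0.984 at CT4 and 0.987 at CT8, and less closely at CT12 (0.963), CT16 (0.972) and CT20 (0.964), across all probe sets of a pair of arrays. Of the 12 arrays, 4 had a narrower spread of values: the SD over probe sets was 2.06 at CT20 of day 1, 2.09 at CT12 of day 2, 2.09 at CT16 of day 2 and 2.12 at CT20 of day 2, against 2.18 to 2.25 on the other 8. These low-spread arrays lay between CT12 and CT20, and together they hold both arrays of CT20. For this reason the number of rhythmic genes, in total and in each gene list, is also given without these 4 arrays and with array spread as a covariate, settings chosen after seeing the data.

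**Figure D1:**
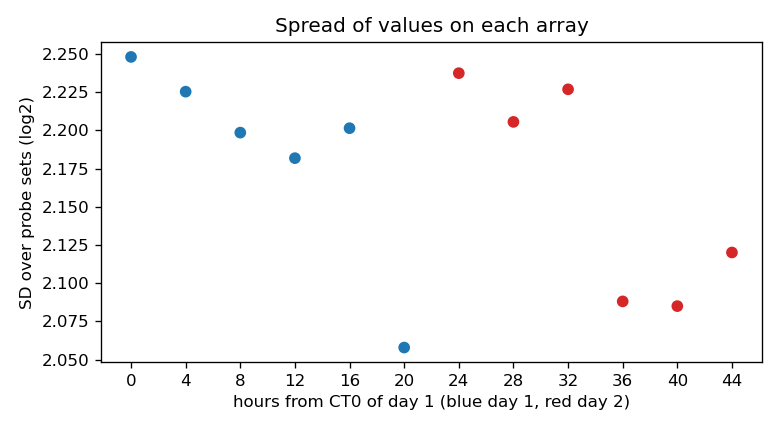
SD of log2 values over all probe sets (vertical axis) of each of the 12 arrays against hours from CT0 of day 1 (horizontal axis), blue for day 1 and red for day 2. The 4 low-spread arrays lie at 2.06 to 2.12 and the other 8 at 2.18 to 2.25.

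The main question of the design was which transcripts follow a 24 h rhythm in macrophages without light cues. The clock itself cycled strongly. Nr1d1, which encodes the repressor REV-ERB alpha, had a peak-to-trough difference of 4.59 ± 0.24 log2 (SE, n = 12), or 24.1-fold, with a fitted peak at CT9.6. Its paralog Nr1d2 varied 7.22-fold with a peak at CT11.1, and Dbp, a clock-controlled transcription factor, varied by 3.32 ± 0.32 log2 with a peak at CT12.1 ± 0.36 h. Arntl, which encodes the activator BMAL1, ran nearly opposite to Dbp, at 2.23 ± 0.16 log2 (4.68-fold) with a peak at CT1.05 ± 0.28 h. In all, 1208 of 19938 genes tested were rhythmic by limma's F test of a 24 h wave at an adjusted p under 0.05.

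The period and cryptochrome genes and Ciart had fitted peaks from CT11.7 to CT18.3, later than Nr1d2, though for Per1 this order is uncertain. Per1 peaked at CT12.6 on day 1 and CT10.7 on day 2, and Nr1d2 at CT11.4 and CT10.9. Per1 peaked at CT11.7 (3.37-fold), Ciart at CT13.2 (3.56-fold), Per3 at CT13.6 (5.07-fold), Cry2 at CT15.1 (2.39-fold), Per2 at CT16.6 (5.44-fold) and Cry1 at CT18.3 (4.45-fold). Of 15 measured core clock genes, 9 were rhythmic over all genes and 11 when adjusted over the list alone. Clock itself, the partner of BMAL1, had a difference of 0.40 ± 0.12 log2 and an adjusted p of 0.110. Rora, Bhlhe40, Bhlhe41, Csnk1d and Csnk1e also did not pass, with adjusted p from 0.0564 for Bhlhe41 to 0.971 for Bhlhe40. Among 6 measured clock output factors, 4 were rhythmic over all genes and 4 when adjusted over the list alone: Dbp, the related factor Tef (3.13-fold, CT13.4), the mitotic kinase gene Wee1 (3.10-fold, CT15.4) and the repressor gene Nfil3 (3.11-fold, CT0.09). Hlf and Usp2 did not pass, at adjusted p = 0.927 and 0.757. Both without the 4 low-spread arrays and with array spread as a covariate, 9 core clock genes and 4 output factors were rhythmic. The mean of the core clock list had a rhythm at adjusted p = 0.00215 in a permutation test over the 12 arrays, and that of the output factors at adjusted p = 0.0190. The mean of the output factors varied by 0.79 ± 0.17 log2, by 0.84 ± 0.19 without the 4 low-spread arrays (exact permutation test, adjusted p = 0.0624) and by 0.87 ± 0.23 with array spread as a covariate (adjusted p = 0.0528), so that the calls ended with wider errors and no smaller wave. It did not pass without the CT4 array of day 1 either (0.0563).

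**Figure D2:**
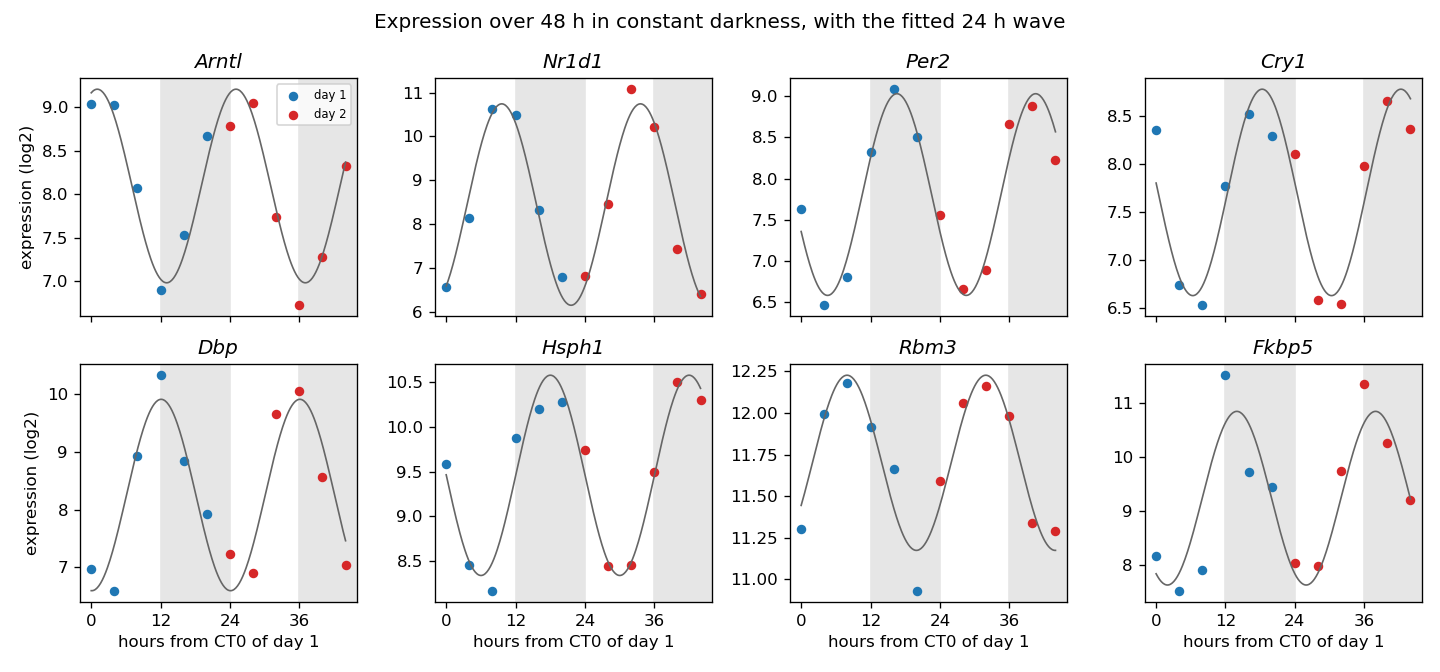
Log2 expression (vertical axes) of 8 genes on the 12 arrays against hours from CT0 of day 1 (horizontal axes), with blue points for day 1, red points for day 2, the fitted 24 h wave as a line and the subjective night shaded. Arntl peaks near CT1.05 and Nr1d1 near CT9.6, and Hsph1 and Rbm3 run nearly opposite to each other.

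Most rhythms were of smaller size than those of the clock. The median peak-to-trough fold of the 1208 rhythmic genes was 1.51 (quartiles 1.39 and 1.69), and 625 genes reached 1.5-fold, 118 reached 2-fold and 12 reached 4-fold. Peaks fell most often between CT4 and CT8 (395 genes) and between CT0 and CT4 (237 genes), and least often between CT12 and CT16 (117 genes). Fitted peaks lay in the subjective day for 63.2% of the rhythmic genes, against 44.6% of all genes tested. That share was 48.9% after another quantile normalization of the arrays, 46.02% without the 4 low-spread arrays and 43.6% with array spread as a covariate. Outside the clock lists, the largest differences belonged to Fkbp5, a co-chaperone of the glucocorticoid receptor (9.18-fold, CT14.0), the tubulin-binding protein genes Tppp3 (7.46-fold, CT20.0) and Tppp (5.56-fold, CT18.2), Pdk4, a brake on glucose oxidation (2.32 log2, CT7.4), and the chaperone gene Hsph1 (4.72-fold, CT18.0). Next came Map3k6, the transcription factor gene Rfx2 (3.82-fold), the amino acid transporter gene Slc7a8 (3.66-fold, CT3.28), the lipoprotein lipase gene Lpl (3.53-fold, CT3.45), Tsc22d3, the chemokine receptor gene Cxcr4 (3.43-fold, CT13.4), Scd2, Car6, Snord14e and Usp17ld, between 3.15-fold for Usp17ld and 3.98-fold for Map3k6.

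The number of rhythmic genes was 954 without the 4 low-spread arrays, of which 601 were among the 1208, and 776 with array spread as a covariate, of which 612 were among the 1208. It depended on the variance model: without a trend of variance on expression level limma called 279 genes, 277 of them among the 1208. With all probe sets tested, 560 probe sets rather than genes were called, 87 of them unnamed and 17 with several gene symbols. With a 12 h wave added, 540 genes passed a joint test of the 24 h and 12 h terms, which does not single out the 24 h wave. The number of rhythmic genes was 453 with the day and linear elapsed time as terms, and 773 without the CT8 array of day 2. At periods of 48, 16, 12 and 9.6 h, the same limma test called 0 genes each, with 490, 447, 450 and 473 genes at an unadjusted p under 0.05 against 4321 at 24 h. These fits left the 24 h wave in the residual, which made them conservative. Only 2.24% to 2.46% of genes had an unadjusted p under 0.05, fewer than that threshold gives without any signal. The 0 calls therefore neither measure false calls at 24 h nor show that other periods are absent.

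**Figure D3:**
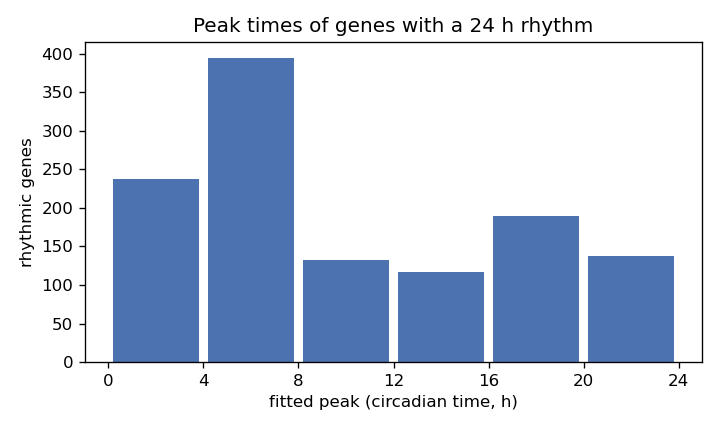
Number of rhythmic genes (vertical axis) by fitted peak in 4 h bins of circadian time (horizontal axis), 1208 genes in all. The tallest bar, from CT4 to CT8, holds 395 genes and the lowest, from CT12 to CT16, holds 117; the share from CT0 to CT12, 63.2% here, was 43.6% with array spread as a covariate.

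Chaperone genes peaked in the subjective night. Of 16 measured heat shock genes, 10 were rhythmic over all genes and 14 when adjusted over the list alone, and all 10 peaked between CT12 and CT24. Hsph1 led, followed by Hspa1a, which encodes the inducible HSP70 (2.13-fold, CT16.8), Dnaja1 (1.87-fold, CT17.4) and the HSP70-HSP90 organising protein gene Stip1 (1.80-fold, CT20.2). The list mean varied by 0.65 ± 0.07 log2 with a peak at CT18.4 (permutation test, adjusted p = 0.00215, n = 12). The cold-inducible RNA-binding protein genes Rbm3 (2.07-fold, CT7.94) and Cirbp (1.93-fold, CT6.23) were both rhythmic, over all genes and adjusted over the list alone, and their mean peaked at CT7.13 (permutation test, adjusted p = 0.00663). Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 8 were rhythmic and 10 when adjusted over the list alone, all 8 with a peak from CT12 to CT24. Examples were Creld2 (1.92-fold, CT19.9), Hspa5, which encodes the chaperone BiP (1.47-fold, CT18.7), Herpud1 (1.58-fold, CT15.4) and Sdf2l1 (1.33-fold, CT21.5). The mean of that list peaked at CT19.8 (permutation test, adjusted p = 0.0192). Without the 4 low-spread arrays 11 heat shock, 2 cold-inducible and 5 unfolded protein response genes were rhythmic, and with array spread as a covariate 12, 2 and 10. The adjusted p of the unfolded protein response mean was 0.0520 without the CT20 array of day 2.

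Genes that respond to glucocorticoids, the adrenal steroids, included some of the largest rhythms. Of 13 measured, 8 were rhythmic over all genes and 9 when adjusted over the list alone, 4 with a peak in the subjective day and 4 in the subjective night. Besides Fkbp5 and Pdk4 they included Tsc22d3, which encodes the anti-inflammatory mediator GILZ (3.51-fold, CT14.6), and the transcription factor gene Klf9 (2.49-fold, CT12.4). The list mean varied by 0.89 ± 0.18 log2 with a peak at CT12.2 (permutation test, adjusted p = 0.00215). Of these genes 7 were rhythmic without the 4 low-spread arrays, and 6 with array spread as a covariate. The list shares 3 members with other lists. Among 16 immediate early genes, 4 were rhythmic and 6 when adjusted over the list alone. They were Jun (1.73-fold, CT16.3), Fos (1.86-fold, CT17.1), Atf3 (1.74-fold, CT16.1) and the phosphatase gene Dusp1 (1.76-fold, CT15.8), while the list mean did not pass (permutation test, adjusted p = 0.269). In the same list 5 genes were rhythmic without the 4 low-spread arrays, and 3 with array spread as a covariate.

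Among the lists of metabolic genes, lipid handling and glycolysis had a rhythmic mean, and oxidative phosphorylation (permutation test, adjusted p = 0.117) and cholesterol synthesis (0.269) did not. Of 22 lipid handling genes, 9 were rhythmic and 10 when adjusted over the list alone, 5 with a peak in the subjective day and 4 in the subjective night. Lpl and Cpt1a, which encodes the gatekeeper of mitochondrial fatty acid uptake (1.96-fold, CT8.58), peaked by day, and the desaturase gene Scd2 (3.30-fold, CT20.5) and the cholesterol exporter gene Abcg1 (2.25-fold, CT19.1) by night. The same number, 9, was rhythmic without the 4 low-spread arrays and with array spread as a covariate. Of 15 glycolysis genes, 6 were rhythmic and 9 when adjusted over the list alone, among them the hexokinase gene Hk2 (1.72-fold, CT20.7), the lactate exporter gene Slc16a3 (1.65-fold, CT22.9), Pgk1 (1.37-fold, CT0.43) and Pfkfb3 (1.80-fold, CT11.3). Of these, 7 were rhythmic without the 4 low-spread arrays and 7 with array spread as a covariate. The means of both lists passed the permutation test, lipid handling at adjusted p = 0.0360 and glycolysis at 0.0495. The lipid handling mean varied by 0.19 ± 0.05 log2, by 0.14 ± 0.05 without the 4 low-spread arrays (exact permutation test, adjusted p = 0.237) and by 0.14 ± 0.06 with array spread as a covariate (0.305). The glycolysis mean varied by 0.20 ± 0.06 log2, by 0.29 ± 0.07 without these arrays (exact permutation test, adjusted p = 0.0675) and by 0.21 ± 0.05 with the covariate (0.0297). With the day as a block the glycolysis mean had an adjusted p of 0.0858, and leaving out 1 array at a time it passed in 2 of 12 fits and the lipid handling mean in 3. Of 48 genes of oxidative phosphorylation 4 were rhythmic and 11 when adjusted over the list alone, with a peak by day (Ndufa3, 1.49-fold; Ndufb7, 1.36-fold), and 1 without the 4 low-spread arrays and 0 with array spread as a covariate. Of 20 cholesterol synthesis genes 1 was rhythmic, Insig1 (1.58-fold, CT5.74), and 5 when adjusted over the list alone; 1 was rhythmic in each of both other fits.

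Genes of immune function were examined in further lists. Of 17 pattern recognition receptors, 4 were rhythmic and 5 when adjusted over the list alone: the beta-glucan receptor gene Clec7a (2.11-fold, CT5.29), the inflammasome sensor gene Nlrp3 (2.21-fold, CT0.59), Tlr1 (1.87-fold, CT5.78) and Tlr6 (1.53-fold, CT6.44). Of the receptors, 5 were rhythmic without the 4 low-spread arrays and 4 with array spread as a covariate. Their mean peaked at CT4.96 (permutation test, adjusted p = 0.0231), and it did not pass without the CT4 array of day 1 (0.0746) or the CT16 array of day 2 (0.0851). It varied by 0.24 ± 0.05 log2, by 0.22 ± 0.08 without the 4 low-spread arrays (exact permutation test, adjusted p = 0.214) and by 0.20 ± 0.07 with array spread as a covariate (0.198). Of 31 genes of TLR4 signalling, the pathway that answers bacterial endotoxin, 1 was rhythmic and 1 when adjusted over the list alone, the inhibitor gene Nfkbia (1.41-fold, CT14.2). Of 19 inflammatory cytokines and mediators, 2 were rhythmic and 3 when adjusted over the list alone, Il1a (2.19-fold, CT0.84) and Ccl3 (1.78-fold, CT4.53). These list means did not pass the permutation test (adjusted p = 0.760 and 0.702). In TLR4 signalling 3 genes were rhythmic without the 4 low-spread arrays and 1 with array spread as a covariate, and among the cytokines and mediators 1 and 0. Of 19 complement and phagocytic receptor genes 3 were rhythmic and 3 when adjusted over the list alone, Mertk, a receptor for apoptotic cells (1.95-fold, CT10.9), its relative Axl (1.65-fold, CT11.8) and Cd36 (1.26-fold, CT8.16), and 4 were rhythmic in each of both other fits. Of 9 genes of MHC class II presentation, 3 were rhythmic and 6 when adjusted over the list alone, namely H2-Oa, H2-Aa and H2-DMa, each between 1.35-fold and 1.55-fold with a peak in the subjective day. B cells also express these genes, and the mean of the B cell markers peaked in the subjective day as well (0.48 log2, CT4.18). The mean of this list peaked at CT8.30 (permutation test, adjusted p = 0.0421; 0.0722 with the day as a block). It varied by 0.38 ± 0.10 log2, by 0.29 ± 0.08 without the 4 low-spread arrays (exact permutation test, adjusted p = 0.135) and by 0.37 ± 0.11 with array spread as a covariate (0.0969), and leaving out 1 array at a time it passed in 4 of 12 fits. In this list 1 gene was rhythmic without the 4 low-spread arrays, and 1 with array spread as a covariate.

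Of 34 proteasome genes 4 were rhythmic and 12 when adjusted over the list alone (Psmc5, 1.41-fold; Psmb6, 1.44-fold), and of 37 cytosolic ribosomal protein genes 1 was rhythmic and 4 when adjusted over the list alone (Rplp0, 1.22-fold). Of 25 lysosome and autophagy genes 2 were rhythmic and 6 when adjusted over the list alone, the cathepsin gene Ctsl (1.87-fold, CT4.47) and the autophagy receptor gene Sqstm1 (1.26-fold). Of 21 interferon-stimulated genes 2 were rhythmic and 2 when adjusted over the list alone, Ifit3 (2.24-fold) and Oas2 (1.51-fold). Of 15 antioxidant genes 2 were rhythmic and 4 when adjusted over the list alone, Gsr (1.42-fold) and Hmox1 (1.30-fold). Of 12 adhesion and migration receptor genes 3 were rhythmic and 8 when adjusted over the list alone, Cxcr4, Pecam1 (1.68-fold) and Cd44 (1.38-fold). Of 27 cell cycle genes 3 were rhythmic and 17 when adjusted over the list alone, Mcm2 (1.53-fold), Cdc6 (1.51-fold) and Ccna2 (1.64-fold). The cell cycle list held 16 rhythmic genes without the 4 low-spread arrays (Fisher's exact test, adjusted p = 1.8e-13, against 0.434 with all arrays), and 2 with array spread as a covariate (0.567). Its mean then varied by 0.55 ± 0.13 and 0.36 ± 0.18 log2, against 0.39 ± 0.15 with all arrays. Fisher's exact test treats these genes as independent, though their estimated correlation was 0.536 in the comparison of days. With arrays as units, the permutation test of the mean gave an adjusted p of 0.0978 without the 4 arrays, 0.341 with the covariate and 0.186 with all arrays. In the same order the counts were 3 and 3 for the proteasome, 0 and 0 for ribosomal proteins, 2 and 2 for lysosome and autophagy, 1 and 1 for interferon-stimulated genes, 0 and 1 for antioxidant genes, and 1 and 1 for adhesion and migration receptors.

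Markers of other cell types were examined because a CD11b enrichment can carry them along. B cell markers moved with time of day: of 17 measured, 8 were rhythmic over all genes and 10 when adjusted over the list alone, all 8 with a peak in the subjective day. They included Cd79a, which encodes a chain of the B cell receptor complex (1.89-fold, CT4.74), its partner Cd79b (1.52-fold), Ms4a1, which encodes CD20 (1.48-fold), Bank1 (1.33-fold), the coactivator gene Pou2af1 (2.13-fold, CT4.10), Cd22 (1.68-fold) and the lineage factor gene Pax5 (1.49-fold). The list mean varied by 0.48 ± 0.13 log2 with a peak at CT4.18 (permutation test, adjusted p = 0.0441). Without the 4 low-spread arrays 3 were rhythmic and the mean varied by 0.35 log2 (exact permutation test, adjusted p = 0.238), and with array spread as a covariate 2 were rhythmic and the mean varied by 0.34 log2 (adjusted p = 0.378). Leaving out 1 array at a time, the mean passed in 3 of 12 fits. Markers of large peritoneal macrophages, the resident population, included Alox15 at a mean of 13.69 log2, Fn1 at 13.61, Prg4 at 12.78 and Adgre1 at 12.71, none of which passed the rhythm test (adjusted p from 0.178 to 0.713). Of 13 such markers 2 were rhythmic and 2 when adjusted over the list alone, the lineage factor gene Gata6 (1.35-fold, CT3.38) and Vsig4 (1.31-fold, CT5.81). Of these markers 1 was rhythmic without the 4 low-spread arrays and 2 with array spread as a covariate. At an unadjusted p under 0.05 there were 8 of the 13, against 10 of the 17 B cell markers. The mean of the large macrophage list also had a daytime peak (0.15 ± 0.06 log2, CT6.31), though it did not pass (permutation test, adjusted p = 0.244).

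The other cell type lists showed at most 1 rhythmic gene each, over all genes and adjusted over the list alone. That gene was Cd226 (1.72-fold) of 11 small peritoneal macrophage and monocyte markers, Cd2 (1.44-fold) of 19 T and NK cell markers, the protease gene Mmp9 (1.99-fold, CT7.31) of 14 neutrophil markers and Flt3 (1.52-fold) of 11 dendritic cell markers. These lists held 3, 0, 1 and 0 rhythmic genes without the 4 low-spread arrays, and 1, 1, 1 and 0 with array spread as a covariate. Among 11 mast cell, 6 eosinophil, 17 mesothelial and fibroblast, 4 erythroid and 6 platelet markers, limma called 0 genes in each list, with 0, 1, 1, 0 and 1 at an unadjusted p under 0.05. In these lists, too, 0 were called in both other fits, except for 1 mesothelial and fibroblast marker without the 4 low-spread arrays. Mean levels of the brightest markers were 11.03 log2 for F13a1 and Retnla, 10.43 for Hdc, 10.44 for Csf3r, 10.92 for Naaa, 11.14 for Pf4, 7.51 for Col1a1, 7.08 for Bpgm and 6.48 for Siglecf. The lists as a whole were dimmer, with mean levels of 5.71 log2 for mast cell, 6.00 for neutrophil, 7.23 for dendritic cell and 7.10 for platelet markers. A single bright gene therefore does not show that its cell type was present.

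Over the 34 lists, 12 held more rhythmic genes than the rest of the array by Fisher's exact test. That comparison was not matched by level. Of the 1208 rhythmic genes, 1136 lay at or above the median level of 6.66 log2, and the 12 lists had mean levels of 7.69 log2 or more. How much of the enrichment reflects level was not tested. Of these 12 lists, 10 were enriched without the 4 low-spread arrays and 9 with array spread as a covariate. B cell markers (Fisher's exact test, adjusted p = 0.109 and 0.352) and MHC class II presentation (0.674 and 0.568) were enriched in neither fit. A rhythmic mean was found in 11 lists. The means of the other 23 lists had adjusted p from 0.117 to 0.918 in the permutation test. Among named genes near the threshold, Rplp0 passed in 6, Flt3 in 7, and Oas2, H2-Aa and H2-DMa in 9 of 25 alternative fits. These 25 include the settings with a narrower p or fold threshold, which were scored on the reported fit, so each gene passed there by construction. Leaving out 1 array, the number of lists with a rhythmic mean fell from 11 to 5 without the CT4 array of day 1 and to 6 without the CT16 array of day 2. It fell to 7 without the CT0, CT8 or CT12 array of day 1 or the CT4 or CT20 array of day 2, and rose to 16 without the CT16 array of day 1. It was 2 without the 4 low-spread arrays (core clock and heat shock, in an exact permutation test of 8 arrays; adjusted p from 0.0607 to 0.238 for the other 9) and 7 with array spread as a covariate. These 7 were core clock, heat shock, cold-inducible, unfolded protein response, glucocorticoid-responsive and glycolysis, and complement and phagocytic receptors (adjusted p = 0.0399), which had not passed before (0.186). With 8 arrays the test has less power, and several means that no longer passed had waves of similar size: unfolded protein response 0.31 ± 0.04 log2 against 0.25 ± 0.04, cold-inducible 1.05 ± 0.18 against 0.98 ± 0.13, and glucocorticoid-responsive 0.85 ± 0.24 against 0.89 ± 0.18.

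**Figure D4:**
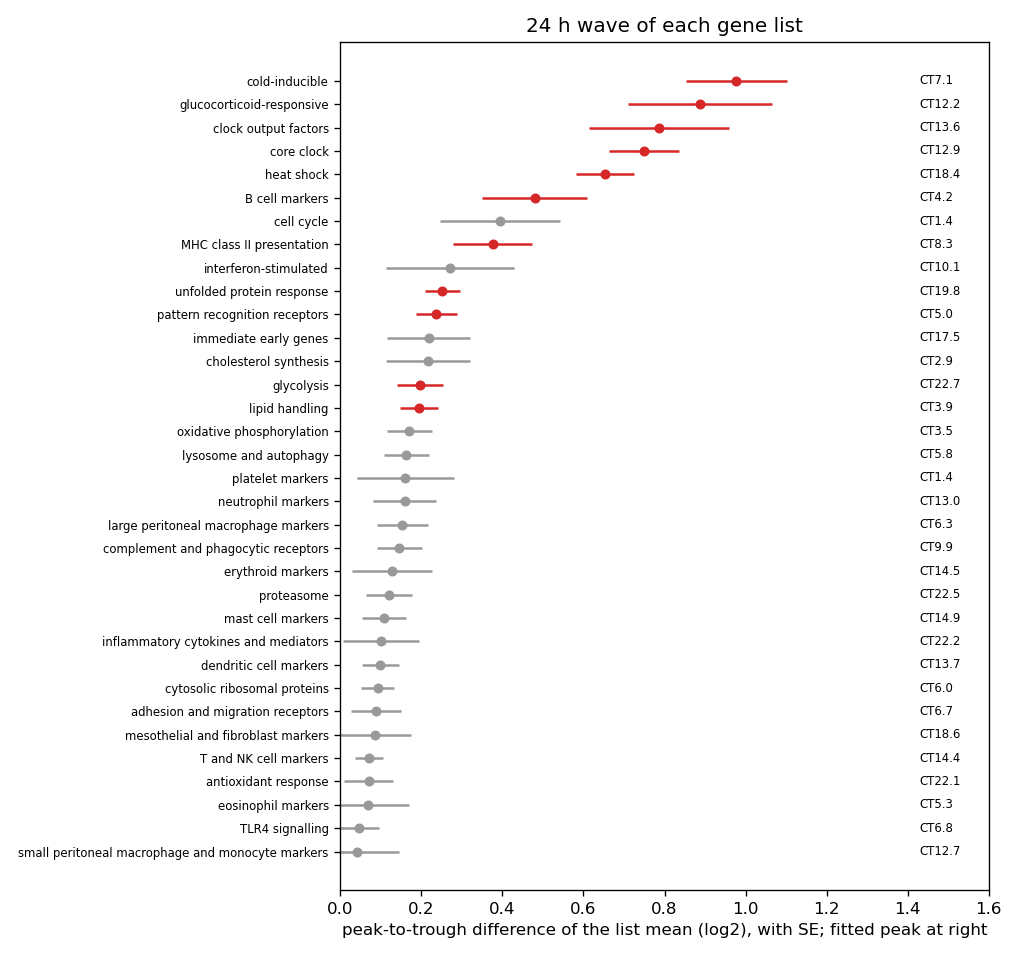
Peak-to-trough difference of the mean of each of the 34 gene lists (log2, horizontal axis, bars give the SE over 12 arrays), red where the permutation test gave an adjusted p under 0.05 and grey otherwise, with the fitted peak at the right. Heat shock peaks at CT18.4 and the cold-inducible pair at CT7.13.

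With no wave shape assumed, 683 genes differed between the 6 circadian times by limma's F test at an adjusted p under 0.05, and 567 of them were among the 1208 rhythmic genes. Arntl averaged 9.04 ± 0.02 log2 at CT4 and 6.81 ± 0.12 at CT12 (SD, n = 2). The number was 767 without the 4 low-spread arrays and 355 with array spread as a covariate. It was 74 without a trend of variance on level, and with all probe sets tested 136 probe sets rather than genes were called. Leaving out 1 array, which left 1 array at its circadian time, moved the number down or up.

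The comparison of day 2 with day 1 asks whether levels drifted in constant darkness. No single gene differed: limma called 0 genes higher and 0 lower on day 2, with 1021 genes (5.12%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.944. A change of 1.5-fold in either direction was seen in 21 genes. As groups, 5 of 34 lists were shifted in limma's camera test with a preset correlation between genes. Cell cycle genes were higher on day 2 in 25 of 27 members by a mean of 0.18 log2 (adjusted p = 1.25e-11 with the preset correlation, 0.839 with the estimated one), with 6 members past the threshold when adjusted over the list alone. Lower on day 2 were oxidative phosphorylation (mean -0.05 log2, adjusted p = 0.00373), lysosome and autophagy (-0.07, 0.000213), B cell markers (-0.13, 0.000811) and small peritoneal macrophage and monocyte markers (-0.12, 0.0365). None of the 5 held with an estimated correlation (adjusted p = 0.839 for each). Of the 4 low-spread arrays 3 were from day 2, and without these arrays cell cycle (adjusted p = 9.79e-06) and small peritoneal macrophage and monocyte markers (adjusted p = 0.0303) remained past the threshold of the preset test while B cell markers (0.227), oxidative phosphorylation (0.108) and lysosome and autophagy (0.183) did not. Another 3 lists passed only then: cholesterol synthesis, higher on day 2 (adjusted p = 1.61e-05), proteasome, lower (0.000828), and interferon-stimulated genes, lower (1.3e-05), whose direction with all arrays was higher (0.120); with an estimated correlation none of the 34 lists passed without the 4 arrays (adjusted p at least 0.716). Which lists passed the preset test thus depended on these arrays. Without them day 2 keeps only CT0, CT4 and CT8, and day 1 keeps CT0 to CT16. That comparison of days is therefore not matched by circadian time and relies on the fitted wave.

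The waves of the clock genes were compared between the days. For the 13 rhythmic clock and output genes, the peak-to-trough difference on day 2 was 0.879 to 1.08 times that on day 1, with a median of 0.962. Their peaks on day 2 came at a median shift of -0.743 h (range -1.94 to 1.005 h) in circadian time, earlier in 10 genes and later in 3. No gene had a different wave on the 2 days by limma's F test (0 genes, with 643 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999). Without the CT16 array of day 2 the test called 2 genes, and without the 4 low-spread arrays 1 gene.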

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

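Chosen after the result was seen were the tests of array spread on B cell markers and on the share of daytime peaks, the comparisons with genes of the same level, the tests of a temperature cycle and of the B cell share, and the way circadian times were drawn at random. The test of array spread on genes with a daytime peak was set when the total still past the threshold, 612 of 1208, was known but not its values by peak time.

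The CT20 array of day 1 lay far from the other 5 arrays of its day in 2 of 4 comparisons within days. Its SD over probe sets was 2.06, with the nearest array at 2.18, and its mean correlation with the other arrays was 0.963, with the nearest at 0.976. Chance marks about 1 in 20 such comparisons. Among 1621 probe sets with several gene symbols, which entered the report only in the count with all probe sets tested, 24 were rhythmic by limma in a fit of their own, 17 in the fit of all probe sets, and 0 in their own fit without the 4 low-spread arrays. Among 12147 unnamed probe sets 0 were in a fit of their own, with 1377 at an unadjusted p under 0.05, and 87 in the fit of all probe sets.

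The rhythm of 1208 genes was set against chance. Of 100 assignments of circadian times within days, the real one included, 1 gave as many rhythmic genes, and the highest other gave 185. Chance alone is therefore unlikely, at 1 of 100, the lowest share these draws can give. Draws over all 12 arrays, made first and replaced because they mixed the days, gave 1 of 100 with a highest other of 470. A level-dependent compression on the 4 low-spread arrays would on average work against the peaks of the 444 genes highest from CT12 to CT24, since other genes of their level shifted on these arrays by a median of -0.0612 log2 (quartiles -0.0748 and -0.0493), except for 28 genes at levels where others were higher; an effect of these arrays that does not depend on level was not excluded for them. In the 764 genes that peaked from CT0 to CT12 the wave with array spread as a covariate was 0.889 times its size at the median (quartiles 0.707 and 1.01), which argues against compression as the whole cause, though only 328 stayed past the threshold and the covariate shares 48.3% of its variance with the wave. The share of daytime peaks fell with this covariate from 63.2% to 43.6%. The 44.6% of all genes came from the fit without the covariate and was not matched by level. These shares therefore do not show how much of the excess compression gives. On the 4 arrays the 764 genes shifted by a median of -0.289 log2 (quartiles -0.383 and -0.195), other genes of their level by -0.0491 (-0.0645 and -0.0317). This argues against a level-dependent compression as the whole source of their shift, though they were picked by their peak. Whether more genes peak by day in macrophages stays open.

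The values argue against a level-dependent compression as the source of the peak of heat shock and unfolded protein response genes in the subjective night, since other genes of the level of their 36 members were lower on the 4 arrays (median shift -0.0908 log2, quartiles -0.143 and -0.0623), while the members were higher by 0.06. A first test of this and of the other nighttime peaks, by array spread as a covariate, gave ratios of 1.12 and 1.01 but could hardly have given less, and is set aside. A daily cycle of body temperature, which was not measured, is a candidate explanation: heat shock and cold-inducible lists peaked 11.3 ± 0.64 h apart, near the antiphase such a cycle predicts, in a test chosen with both peaks known. Stress during cell isolation at some times stays open. The day 1 deviations of heat shock and immediate early genes from their circadian-time means correlated at r = 0.23 over 6 times (exact permutation p = 0.643). Spearman's rho was -0.14 (exact permutation p = 0.803), r was -0.76 without the 2 farthest times, and 1 relation was tested. Stress that recurs at the same times on both days would lie in the circadian-time means, which these deviations leave out. Of 16 immediate early genes 4 were rhythmic, with peaks from CT15.8 to CT17.1, near that of the heat shock mean at CT18.4. The mean of the immediate early list did not pass (permutation test, adjusted p = 0.269).

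For the daytime peak of B cell markers, a varying share of B cells among the sorted cells and an effect of the 4 arrays cannot be told apart. That 15 of 17 markers peaked within 6 h of the mean of the others (15 also against the list mean, the first form of this test) follows from either. With array spread as a covariate the wave was 0.790 times its size at the median with quartiles of 0.496 and 1.003. On the 4 arrays the markers shifted by a median of -0.34 log2 (quartiles -0.484 and -0.230), other genes of their level by -0.06 (-0.0588 and -0.0304). These shifts argue against a level-dependent compression as the whole source of the peak, but not against another effect of these arrays. The brightest B cell genes were Cd79b at 10.14, Bank1 at 9.74 and Ms4a1 at 9.54 log2, and 0 of the 17 stand in another list. Among markers of other cells, Hdc, Csf3r and Naaa did not pass the rhythm test (limma, adjusted p = 0.381, 0.676 and 0.992). The neutrophil marker Mmp9 did, with a daytime peak (1.99-fold, CT7.31, limma, adjusted p = 0.00131). The mast cell and neutrophil lists had mean levels of 5.71 and 6.00 log2, so Hdc and Csf3r alone do not measure the share of those cells. The dendritic cell mean varied by 0.10 ± 0.05 log2 with a fitted peak at CT13.7, and Gata6 and Vsig4 of large macrophages peaked by day.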

How the results depend on the processing

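The fits without the 4 low-spread arrays and with array spread as a covariate were chosen after seeing the data; all others were set before the data were examined. The count of rhythmic genes, 1208, was 1607 with a filter on dim genes, 1171 with probe set means, 1255 after quantile normalization, 1061 after median centring, 1570 with array weights and 954 without the 4 low-spread arrays. With all probe sets tested, 560 probe sets rather than genes were called. The count of genes was 279 without a variance trend and 540 with a 12 h wave added and both waves tested jointly. It was 453 with the day as a replicate block and linear elapsed time, and 776 with array spread as a covariate. It was 453 at an adjusted p under 0.01 and 625 with a fold of at least 1.5. Linear elapsed time within a day shares 68.6% of its variance with the wave, and the last pair of settings only narrow the threshold; for the others the cause was not tested. Leaving out 1 array gave 773 to 1686. The count of genes differing between circadian times, 683, was 74 without a variance trend and 355 with array spread as a covariate. It was 297 to 1119 leaving out 1 array, where the lone array of a time was assumed to vary like the others. With all probe sets tested, 136 probe sets rather than genes differed between circadian times. The day 2 against day 1 counts were 0 by limma in each alternative, with 1021 genes at an unadjusted p under 0.05 in the reported fit. Genes whose rhythm differed between days numbered 0 to 2 leaving out 1 array and 1 without the 4 low-spread arrays. Lists with a rhythmic mean numbered 11, and 9 after median centring, 5 to 16 leaving out 1 array, 2 without the 4 low-spread arrays and 7 with array spread as a covariate. Without those 4 arrays no array of CT20 is left. Lists shifted between days numbered 5, and 0 with an estimated correlation, with all arrays or without the 4 low-spread arrays (the latter chosen after seeing the data).

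With the day as a replicate block 1198 genes were rhythmic, 724 differed between circadian times, 9 list means were rhythmic (glycolysis and MHC class II no longer passed) and 10 lists were enriched for rhythmic genes in place of 12. Of 95 named rhythmic genes 42 passed in each alternative fit, and over their 2371 alternative fits 1998 passed and 0 reversed phase. Signal over background was not given for these values, so dim genes limit the rest: 1136 of the 1208 rhythmic genes lay at or above the median level of 6.66 log2.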

Other observations

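The genes of this part were chosen after their values were seen, the first from the 30 of smallest p outside all 34 lists, and the draws at its end were remade after a first set was seen. Of these 30, 16 peaked in the subjective day and 14 in the subjective night, and no functional group was tested among them. Genes with a peak by day included the eosinophil-attracting chemokine gene Ccl24 (2.61-fold, CT5.78), the arginine-degrading enzyme gene Arg1 (2.85-fold, CT3.67), Cd180, a relative of the Toll-like receptors (1.84-fold, CT5.42), the costimulatory ligand gene Cd86 (1.84-fold, CT7.45), the lectin receptor gene Clec5a (3.02-fold, CT6.54) and Rgs2, a regulator of G protein signalling (2.12-fold, CT4.78). Each of these passed without the 4 low-spread arrays and with array spread as a covariate, with limma's adjusted p at most 0.00625 (Arg1).

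Genes with a peak by night included Ahsa1 (1.71-fold, CT18.1) and Fkbp4 (1.91-fold, CT19.5), which encode co-chaperones of HSP90, the collagen-modifying enzyme gene P4ha1 (2.10-fold, CT18.8), the nuclear lamina gene Lmna (1.14 log2, CT18.7) and the membrane-cytoskeleton linker gene Ezr (2.03-fold, CT19.5).

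Some genes differed between circadian times without passing as a wave, 116 in all. Il15ra, which encodes the receptor that presents interleukin 15, averaged 9.01 ± 0.32 log2 at CT12 and 7.98 ± 0.15 at CT8 (SD, n = 2), though it missed the wave threshold narrowly (limma, adjusted p = 0.0502). The copper transporter gene Slc31a2 averaged 10.54 ± 0.13 at CT12 and 9.81 ± 0.05 at CT8 (adjusted p of the wave 0.184 by limma). Nfkbiz averaged 8.99 ± 0.06 at CT4 and 8.30 ± 0.04 at CT0 (adjusted p of the wave 0.0613 by limma).

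For the 683 genes that differed between circadian times, 1 of 100 assignments of circadian times within days gave as many, the real one included, and the highest other gave 348. At an unadjusted p under 0.05 the highest other gave 3231 genes, close to the real 3556. By the count of adjusted calls chance alone is unlikely, at 1 of 100, the lowest share these draws can give. The unadjusted counts separate the real times from chance less clearly. Draws over all 12 arrays, made first, gave 1 of 100 with a highest other of 130. For day 2 against day 1 and for rhythms that differ between days, the real counts were 0, so that 100 of 100 drawn splits (of 462 possible) gave as many. The highest other counts were 15 and 16 (15 and 40 in the draws made first, which allowed repeats). Unlike the real days, these splits were not matched by circadian time, so they are an imperfect reference for a day difference. At an unadjusted p under 0.05, 33 and 78 of the 100 gave as many genes as the real 1021 and 643, so chance cannot be excluded for these. The highest other splits reached 2686 and 2354 genes; what these splits share was not tested.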
